A study of Homo sapiens with 18 samples.

How the data were processed

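Messenger RNA was measured in 3 established human acute myeloid leukemia cell lines that carry FLT3 mutations, MV4-11, Molm-13 and Molm-14. Cells were exposed for 48 h to 200 nM of the compound TP-0184 or left untreated, and each of the 6 groups held 3 libraries, per the labels. The labels give no vehicle and no culture time for the untreated cells. They do not say whether replicates came from separate cultures, so every p-value measures the spread between these libraries alone. Libraries were made with a stranded poly(A) kit, and the strand setting used for counting was not stated.

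The deposited table held a raw count and an FPKM value per gene and library for 60612 Ensembl genes. Per the submitters' processing notes, reads were trimmed with cutadapt, checked with FastQC, aligned with HISAT2 and assembled with StringTie, and edgeR was used for differential expression, all without stated versions. The genome build was not given in the sources used here. Of 58394 gene identifiers shared with GENCODE 29, 42468 (72.7%) had the same chromosome, start and end, and coordinates below are those of the deposited table. Symbols were read from the gene name column of the deposited table. Genes ranked by the size of a change or difference were named only if their description cited an HGNC symbol. All count values were whole numbers, and 28445 genes had no count in any library. Counts of 4, 8 and 12 made up 22.2%, 12.2% and 6.55% of the values from 1 to 12, an excess seen when reads are derived from assembled coverage. The deposited FPKM value was 1e-04 wherever the count was 0, and FPKM values were used only in an alternative test.

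Library totals were 59327514, 51279600 and 60122117 counts in treated MV4-11 and 72053031, 71246980 and 53349288 in untreated MV4-11. They were 64340266, 73622867 and 65629296 in treated Molm-13 and 51812443, 57287239 and 54419860 in untreated Molm-13. In Molm-14 they were 69753335, 67954930 and 72150480 in treated and 69534592, 72558912 and 60017679 in untreated libraries. A floor of 3 counts per library corresponded to 0.0407 to 0.0585 CPM, the count scaled to the library total. Floors cover counting error only.

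Counts were analyzed in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood negative binomial test. Genes were kept by the filterByExpr function (20533 genes), libraries were scaled by TMM factors, and 1 model with 6 groups and 18 libraries was fitted, which left 12 residual degrees of freedom. Treated libraries were compared with untreated libraries within each line, and the difference between the responses of each pair of lines was tested as a contrast of the same model. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Log2 fold changes are treated over untreated with a prior count of 0.125, and their standard error (SE) is the change divided by the square root of the F statistic. CPM values are TMM-scaled means ± SD of 3 libraries.

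A total of 41 gene lists with 849 symbols was written before the data were examined. All symbols but 1 were matched to the table, 2 of them by an older name. Lists of at least 5 tested members were compared with all other tested genes by the camera test of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01, and again with an estimated correlation. The number of members that passed was also counted with p-values adjusted over the list alone. The rule for naming genes was fixed before the data were examined as well. It takes all members of the receptor list and 2 to 4 called members per list with the largest mean change in the direction of the list. It also takes the 8 largest rises and 8 largest falls per line, the 12 most changed shared rises and falls over all 3 lines ranked by the smallest of the 3 changes, and the 4 genes per pair of lines with the largest difference among genes called in opposite directions. Up to 5 list members that moved against the rest were named after their values were seen. Apart from the receptor list, genes named by the rule needed a mean of at least 5 CPM in the higher group, and those ranked within 1 line also an absolute log2 fold change of at least 1 and no overlap between treated and untreated libraries.

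The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 3 libraries, a fit of only the libraries compared, the replicate number as a block, limma on log2 FPKM with an added 1 or 0.1, a required 2-fold change, the fry test for lists, and leaving out each library in turn. A robust fit, scaling by library totals alone, a restriction to genes without overlap between groups and list tests on differences between lines were added after the data had been seen. The procedure was tested on simulated data with the same depths, where edgeR recovered 92.4% of genes changed 4-fold, 58.2% of genes changed 2-fold and 19.4% of genes changed 1.5-fold in MV4-11, with 2 wrong calls. The corresponding shares were 86.4%, 53.7% and 31.3% with 8 wrong calls in Molm-13, and 89.4%, 49.3% and 16.4% with 7 wrong calls in Molm-14. Only 66 or 67 genes per fold and line and 1 list of 30 genes were changed there. In the data 38.5%, 29.9% and 10.9% of genes were called in MV4-11, Molm-13 and Molm-14. Simulated counts also followed the spread that edgeR had fitted. The shares and wrong calls therefore do not measure performance on the data themselves. No library was left out.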

Results

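The data comprised 18 libraries from MV4-11, Molm-13 and Molm-14 cells, with 3 treated and 3 untreated libraries per line and 51279600 to 73622867 counts per library. The series title concerns joint targeting of FLT3 and ACVR receptors in acute myeloid leukemia, and each comparison addressed which transcripts differed after exposure to TP-0184. The first principal component of the tested genes held 35.1% of the variance and the second 17.7%. Molm-14 libraries lay at 123 to 135 on the first component, and those of the other lines at −84.5 to −44.9. All 18 libraries correlated most closely with another library of their own group. FLT3 (ENSG00000122025) lies on chromosome 13 from 28003274 to 28100592, KIT (ENSG00000157404) on chromosome 4 from 54657918 to 54739011, CSF1R (ENSG00000182578) on chromosome 5 from 150053291 to 150113372, and ACVR1 (ENSG00000115170) on chromosome 2 from 157736444 to 157876330.

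In MV4-11, TP-0184 was followed by higher mRNA of several hematopoietic receptor kinases. FLT3, the mutated growth factor receptor of these cells, rose from 328 ± 41.9 to 660 ± 76.3 CPM (log2 fold change 1.01 ± 0.10 SE, n = 3 per group, adjusted p = 1.4e-06). KIT, the stem cell factor receptor, rose from 1.04 ± 0.29 to 28.6 ± 3.42 CPM (4.78 ± 0.59, adjusted p = 1.22e-05). The kinase PIM1, induced downstream of FLT3 and STAT5, fell from 242 ± 8.4 to 82.8 ± 9.6 CPM (−1.54 ± 0.09, adjusted p = 7.12e-09). The cyclins CCND2 (−1.63 ± 0.10) and CCND3 (−1.87 ± 0.12), which drive entry into the cell cycle, fell as well. The list of STAT5 targets that holds these genes was not called in MV4-11. Of its 14 genes 3 fell (PIM1, CCND2 and CCND3) and 3 rose (PIM2, BCL6 and GFI1), the same counts when adjusted over the list alone. The median was −0.20, or 0.0161 with scaling by library totals alone (list adjusted p = 0.173, adjusted p = 0.223 with an estimated correlation). The macrophage colony-stimulating factor receptor CSF1R (1.75 ± 0.10), the receptor kinase AXL (2.45 ± 0.13) and the TGF-beta receptor TGFBR2 (1.04 ± 0.12) rose. ACVR1, a BMP and activin receptor kinase of the ACVR family, rose from a low level of 3.31 ± 0.757 to 6.09 ± 1.32 CPM (0.88 ± 0.22, adjusted p = 0.00492). ACVRL1, an endothelial BMP receptor, fell (−1.30 ± 0.25). BMPR1A rose (1.09 ± 0.25, adjusted p = 0.00229, with a range of 9.47e-05 to 0.0738 over the alternatives, the highest and only loss with limma on log2(FPKM + 1)). BMPR2 rose by 0.59 ± 0.17 (adjusted p = 0.0115), but its libraries overlapped. The BMPR2 call was lost without treated replicate 2 (0.0514) or untreated replicate 1 (0.0597) and with only the libraries compared (0.0965), with a range of 0.00114 to 0.0965 over the alternatives. Of the 14 receptor and ligand genes tested, 8 rose and 1 fell, the same counts when adjusted over the list alone. The median was 0.94 (list adjusted p = 0.0083, adjusted p = 0.117 with an estimated correlation).

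**Figure D1:**
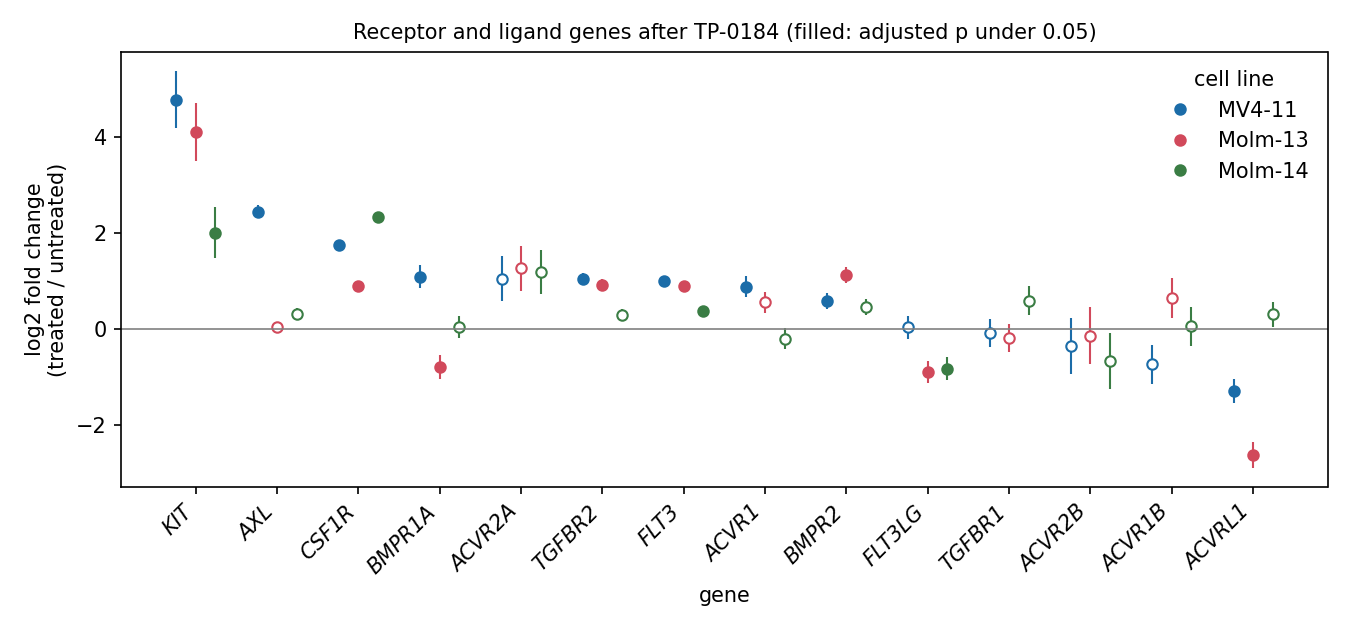
Log2 fold change (treated over untreated, ± SE, 3 libraries per group) of the 14 tested receptor and ligand genes in each line, with filled points for adjusted p under 0.05. FLT3, KIT and CSF1R lie above 0 in all 3 lines, from 0.38 for FLT3 in Molm-14 to 4.78 for KIT in MV4-11.

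Targets of the MAPK pathway moved down in MV4-11, led by the ETS factor ETV4 (−2.97 ± 0.22), with the feedback inhibitor SPRY2 (−1.57 ± 0.15) also lower. Over this list 9 of 17 genes fell and 2, PHLDA1 and DUSP6, rose, with the same counts when adjusted over the list alone. The median was −0.42 (list adjusted p = 0.00147, adjusted p = 0.0587 with an estimated correlation). Genes of DNA replication were lower almost throughout, with CDC45 (−1.68 ± 0.09), RFC3 (−1.55 ± 0.12), RFC4 (−1.06 ± 0.11) and the licensing factor CDT1 (−0.96 ± 0.10) among them. Of 38, 37 fell over all genes and when adjusted over the list alone. The median was −1.05 (list adjusted p = 1.39e-19, adjusted p = 0.0677 with an estimated correlation). Mitotic genes fell in 29 of 36 cases by both counts, over all genes and adjusted over the list alone. UBE2C (−1.21 ± 0.11) and MAD2L1 (−1.22 ± 0.10) were among them. The median was −0.90 (list adjusted p = 8.18e-13, adjusted p = 0.122 with an estimated correlation). Ribosome biogenesis genes of the MYC program fell in 30 of 33 cases by both counts, over all genes and adjusted over the list alone. They included the nucleolar chaperone NPM1 (−1.01 ± 0.10) and MRTO4 (−1.35 ± 0.08). The median was −0.82 (list adjusted p = 6.19e-13, adjusted p = 0.012 with an estimated correlation).

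Metabolic genes of MV4-11 fell on several branches. The amino acid response controlled by the stress factor ATF4 fell in 23 of 29 genes and rose in 1, VLDLR, with the same counts when adjusted over the list alone. The median was −0.88 (list adjusted p = 2.1e-10, adjusted p = 0.00904 with an estimated correlation). Its members included STC2 (−4.76 ± 0.16), the cysteine pathway enzyme CBS (−3.29 ± 0.15, with a near-identical copy, CBSL), the pseudokinase TRIB3 (−2.81 ± 0.15), the serine synthesis enzyme PHGDH (−2.33 ± 0.17) and the glutathione-degrading enzyme CHAC1 (−2.64 ± 0.26). Cholesterol synthesis fell in 20 of 24 genes by both counts, over all genes and adjusted over the list alone, among them ACAT2 (−1.53 ± 0.08) and FDPS (−0.85 ± 0.09). The median was −0.76 (list adjusted p = 2.01e-07, adjusted p = 0.00904 with an estimated correlation). The desaturase SCD (−1.84 ± 0.08), the glucose transporter SLC2A3 (−1.53 ± 0.07) and the respiratory chain subunit CYC1 (−1.33 ± 0.12) fell, and TXNIP, a brake on glucose uptake, rose (1.78 ± 0.07). Nuclear genes of oxidative phosphorylation fell in 42 of 50 cases, or 45 adjusted over the list alone. The median was −0.68 (list adjusted p = 5.13e-15, adjusted p = 0.176 with an estimated correlation).

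Genes of myeloid identity separated in MV4-11. Neutrophil granule genes fell, with MPO (−3.03 ± 0.12), PRTN3 (−2.09 ± 0.15) and ELANE (−1.68 ± 0.15) in front. Of 16 such genes 12 fell and 2, MS4A3 and CFD, rose by both counts, over all genes and adjusted over the list alone. The median was −1.0 (list adjusted p = 2.79e-06, adjusted p = 0.199 with an estimated correlation). Genes of dendritic cells and antigen presentation rose in 12 of 19 cases and fell in 2 (CD83 and BATF3), or 3 adjusted over the list alone. HLA-DRA stood at 2.47 ± 0.14 and HLA-DRB1 at 2.76 ± 0.37. The median was 1.3 (list adjusted p = 0.00625, adjusted p = 0.0957 with an estimated correlation). Inflammatory targets of NF-kappaB fell in 12 of 23 cases and rose in 1 (TRAF1), or 14 and 2 adjusted over the list alone. The cytokine TNF (−1.20 ± 0.10) and the chemokines CCL5 (−3.08 ± 0.22) and CCL2 (−2.76 ± 0.39) fell. The median was −0.66 (list adjusted p = 0.000848, adjusted p = 0.0159 with an estimated correlation). The largest rises included IGF1 (5.58 ± 0.73, with an overlapping transcript on the opposite strand), COL24A1 (5.37 ± 0.45) and IRF4 (4.93 ± 0.47), and the largest falls ORM1 (−6.77 ± 0.59), KRT17 (−4.61 ± 0.64) and the kinase FYN (−4.38 ± 0.20). In all, 3931 genes were higher and 3967 lower, 38.5% of those tested. Of all tested genes, 47.1% had no overlap between groups, where chance gives 10%. Scaling by library totals alone moved the median of all genes by 0.223 and gave 5444 higher and 2690 lower genes (66.9% higher against 49.8%).

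**Figure D2:**
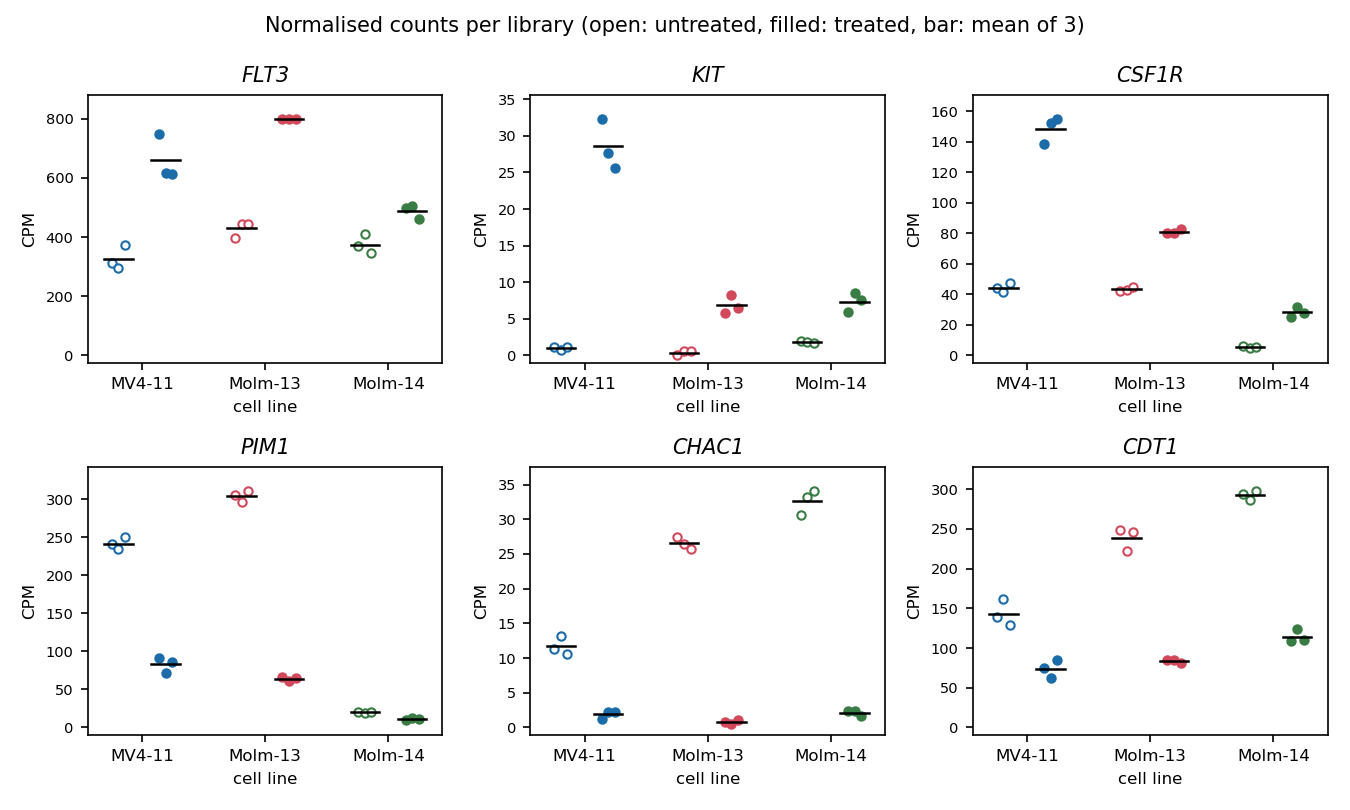
CPM of FLT3, KIT, CSF1R, PIM1, CHAC1 and CDT1 in each of the 18 libraries, with open points for untreated and filled points for treated libraries and a bar at the mean of 3. In all 3 lines the treated libraries lie above the untreated ones for the 3 receptors and below them for PIM1, CHAC1 and CDT1.

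In Molm-13, FLT3 and KIT were higher and the amino acid response fell further than in MV4-11. FLT3 rose from 430 ± 27.4 to 800 ± 0.467 CPM (0.90 ± 0.10, n = 3 per group, adjusted p = 1.07e-05) and KIT from 0.39 ± 0.338 to 6.83 ± 1.25 CPM (4.11 ± 0.60, adjusted p = 0.000108). PIM1 fell from 304 ± 7.87 to 64.3 ± 2.62 CPM (−2.24 ± 0.09, adjusted p = 5.95e-10). The list of STAT5 targets fell in 5 of 14 genes and rose in 1, or 6 and 1 adjusted over the list alone. Its median was −0.44 (list adjusted p = 0.0196, adjusted p = 0.0767 with an estimated correlation). CHAC1 fell from 26.6 ± 0.893 to 0.792 ± 0.293 CPM (−5.07 ± 0.29, adjusted p = 1.53e-08). CSF1R (0.90 ± 0.10), TGFBR2 (0.92 ± 0.12) and BMPR2 (1.13 ± 0.17) rose, and ACVRL1 fell (−2.63 ± 0.26). AXL stood at 0.03 ± 0.12 (adjusted p = 0.9). ACVR1 was 0.56 ± 0.22 (adjusted p = 0.0687). It passed with DESeq2 (0.0359), the CPM filter (0.0431), limma on log2(FPKM + 1) (0.0235) or log2(FPKM + 0.1) (0.0147) and library totals alone (0.0157). It also passed without MV4-11 untreated replicate 3 (0.0499) or Molm-13 untreated replicate 2 (0.0237), with a range of 0.0147 to 0.25 over the alternatives. FLT3LG, the ligand of FLT3, fell by 0.90 ± 0.24 (adjusted p = 0.00985, range 0.00151 to 0.0545). This call was lost without treated replicate 3 (0.0545). BMPR1A fell by 0.80 ± 0.25 (adjusted p = 0.0272, range 0.0175 to 0.729). The BMPR1A call was lost without treated replicate 1 (0.0814), 2 (0.0768) or 3 (0.0597) or untreated replicate 2 (0.116). It was also lost with limma on log2(FPKM + 1) (0.729) or log2(FPKM + 0.1) (0.287) and library totals alone (0.0761). Of 14 receptor and ligand genes 5 rose and 3 fell, or 7 and 3 adjusted over the list alone. The median was 0.60 (list adjusted p = 0.129, and 0.332 with an estimated correlation).

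The ATF4 program of Molm-13 fell in 25 of 29 genes, or 28 adjusted over the list alone. The median was −1.59 (list adjusted p = 1.5e-25, adjusted p = 0.00021 with an estimated correlation). Beside CHAC1 it included CTH (−3.06 ± 0.21), which makes cysteine, STC2 (−2.94 ± 0.14), SESN2 (−1.89 ± 0.12), a sensor of leucine, and ASS1 (−2.06 ± 0.10), an enzyme of arginine synthesis. The amino acid and creatine carriers SLC6A9 (−5.47 ± 0.36) and SLC6A8 (−4.61 ± 0.29) and the activin subunit gene INHBE (−5.48 ± 0.54) were among the largest falls, with the signaling regulators RGS16 (−4.58 ± 0.14) and RGS1 (−4.38 ± 0.39). Glycolytic genes fell in 18 of 25 cases and rose in 1 (HK3) by both counts, over all genes and adjusted over the list alone. The median was −0.83 (list adjusted p = 1.2e-09, adjusted p = 0.0326 with an estimated correlation). SLC2A3 (−2.45 ± 0.07), LDHA (−1.31 ± 0.09) and PFKFB4 (−3.08 ± 0.13) were among them. Hypoxia-responsive genes fell in 10 of 15 cases and rose in 1 (KDM3A), or 11 and 1 adjusted over the list alone. The median was −1.53 (list adjusted p = 4.63e-09, adjusted p = 0.00448 with an estimated correlation). The angiogenic factor VEGFA (−2.01 ± 0.27) and the mitophagy gene BNIP3 (−1.85 ± 0.12) were lower. Cholesterol synthesis fell in 20 of 24 genes, including ACAT2 (−1.86 ± 0.08), FDPS (−1.64 ± 0.09) and HMGCS1 (−1.52 ± 0.23). Adjusted over the list alone, 20 fell and 1 rose. The median was −0.79 (list adjusted p = 3.94e-11, adjusted p = 0.000769 with an estimated correlation).

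Proliferation genes of Molm-13 were lower for replication and mixed for mitosis. CDC45 (−1.45 ± 0.09), CDT1 (−1.52 ± 0.11) and RFC4 (−1.34 ± 0.11) were among 31 of 38 replication genes that fell, or 34 adjusted over the list alone. The median was −0.87 (list adjusted p = 5.91e-21, adjusted p = 0.051 with an estimated correlation). Mitotic genes fell in 15 of 36 cases and rose in 1 (CENPE), or 15 and 4 adjusted over the list alone. Their median of −0.13 became 0.0255 with scaling by library totals alone (list adjusted p = 0.0449, adjusted p = 0.642 with an estimated correlation). MYC program genes fell in 20 of 33 cases and rose in 1 (TWNK), or 23 and 3 adjusted over the list alone, with NPM1 at −0.66 ± 0.10. The median was −0.46 (list adjusted p = 3.47e-07, adjusted p = 0.0487 with an estimated correlation). MAPK targets fell in 7 of 17 cases, or 9 adjusted over the list alone, with ETV4 at −1.55 ± 0.21 and ETV5 at −1.14 ± 0.10, the latter overlapping another gene on the same strand. The median was −0.86 (list adjusted p = 4.19e-05, adjusted p = 0.0157 with an estimated correlation). Genes of cell cycle arrest and quiescence rose in 11 of 20 cases and fell in 1 (KLF2) by both counts, over all genes and adjusted over the list alone, with SESN3 at 1.17 ± 0.16. The median was 0.57 (list adjusted p = 0.000403, adjusted p = 0.0407 with an estimated correlation). Targets of KMT2A fusions rose in 10 of 22 cases by both counts, over all genes and adjusted over the list alone, with the leukemia factor MEIS1 (1.07 ± 0.08) and JMJD1C (1.64 ± 0.24) among them. The median was 0.39 (list adjusted p = 0.000853, adjusted p = 0.0819 with an estimated correlation). The largest rises included the immunoglobulin gene IGHM (6.57 ± 0.54), COL24A1 (5.49 ± 0.46), ADAM28 (4.26 ± 0.45) and the scavenger receptor CD36 (3.74 ± 0.19). In all, 3027 genes were higher and 3108 lower, 29.9% of those tested. Of all tested genes, 48.6% had no overlap between groups, against 10% by chance. Scaling by library totals alone moved the median of all genes by 0.151 and gave 3918 higher and 2115 lower genes (64.9% higher against 49.3%).

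In Molm-14, the amino acid response fell as in the other lines and monocyte genes rose. CHAC1 fell from 32.6 ± 1.82 to 2.12 ± 0.461 CPM (−3.94 ± 0.27, n = 3 per group, adjusted p = 1.83e-07), and STC2 from 51.1 ± 2.98 to 3.93 ± 0.504 CPM (−3.70 ± 0.14, adjusted p = 5.67e-10). CSF1R, the receptor that sustains monocytes, rose from 5.59 ± 0.706 to 28.3 ± 3.26 CPM (2.34 ± 0.10, adjusted p = 1.75e-09), and its gene overlaps a ribosomal pseudogene on the opposite strand. PIM1 fell from 19.8 ± 0.539 to 11.6 ± 1.37 CPM (−0.77 ± 0.09, adjusted p = 3.75e-05), and CCND2 fell (−1.14 ± 0.10). The STAT5 target list was not called, with 3 of 14 genes lower and 1 higher, the same counts when adjusted over the list alone. Its median was −0.16 (list adjusted p = 0.0841, adjusted p = 0.139 with an estimated correlation). FLT3 rose from 375 ± 32.2 to 488 ± 24.4 CPM (0.38 ± 0.10, adjusted p = 0.022). The FLT3 call was lost without treated replicate 1 (0.0722) or 2 (0.0798) or untreated replicate 1 (0.0732) or 3 (0.105), with a range of 0.00442 to 0.105 over the alternatives. It was also lost with the replicate block (0.0703), limma on log2(FPKM + 1) (0.064) or log2(FPKM + 0.1) (0.065) and library totals alone (0.0673). KIT rose from 1.82 ± 0.144 to 7.33 ± 1.34 CPM (2.01 ± 0.53, adjusted p = 0.0222, range 2.68e-05 to 0.0839). The KIT call was lost without treated replicate 2 (0.0665) or 3 (0.0568) or untreated replicate 1 (0.0658), 2 (0.0702) or 3 (0.0816), and with the replicate block (0.0839). FLT3LG fell by 0.83 ± 0.24 (adjusted p = 0.0359, range 0.00537 to 0.137). The FLT3LG call was lost without treated replicate 1 (0.0836) or 3 (0.119), untreated replicate 2 (0.089) or 3 (0.137), or Molm-13 untreated replicate 2 (0.0505). It was also lost with no low-count filter (0.0572), the replicate block (0.129) and only the libraries compared (0.0905). ACVR1 stood at −0.20 ± 0.22 (adjusted p = 0.669) and AXL at 0.32 ± 0.12 (adjusted p = 0.117). Of 14 receptor and ligand genes 3 rose and 1 fell, or 7 and 1 adjusted over the list alone. The median was 0.31 (list adjusted p = 0.0355, adjusted p = 0.142 with an estimated correlation).

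The ATF4 program fell in 28 of 29 genes of Molm-14, or 29 adjusted over the list alone. The median was −1.54 (list adjusted p = 4.1e-52, adjusted p = 4.66e-06 with an estimated correlation). CBS (−3.17 ± 0.14), TRIB3 (−2.97 ± 0.15), CTH (−2.49 ± 0.20), PHGDH (−1.97 ± 0.17), ASS1 (−2.12 ± 0.10), SLC6A9 (−4.79 ± 0.35) and INHBE (−4.90 ± 0.51) fell. The calcium-binding protein gene S100P fell as well (−4.15 ± 0.26). Monocyte and macrophage genes rose in 12 of 28 cases and fell in 1 (FCGR1A), or 13 and 1 adjusted over the list alone. The median was 0.65 (list adjusted p = 4.68e-07, adjusted p = 0.00803 with an estimated correlation). The calprotectin genes S100A8 (2.57 ± 0.24) and S100A9 (1.57 ± 0.16), lysozyme LYZ (0.91 ± 0.09) and the fractalkine receptor CX3CR1 (1.11 ± 0.09) rose. Lysosomal and autophagy genes rose in 10 of 29 cases, or 16 adjusted over the list alone, including the lysosomal proteins GRN (1.09 ± 0.17) and PSAP (0.89 ± 0.08). The median was 0.32 (list adjusted p = 1.42e-06, adjusted p = 0.129 with an estimated correlation). HLA-DRA (1.77 ± 0.14), the leukocyte gene LSP1 (2.86 ± 0.13), the sorting receptor SORL1 (2.10 ± 0.17) and the homing receptor CXCR4 (1.02 ± 0.08) rose, as did the transferrin receptor TFRC (1.42 ± 0.15).

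Replication genes of Molm-14 showed little change as a list, although CDT1 fell from 293 ± 5.61 to 114 ± 8.34 CPM (−1.36 ± 0.10, n = 3 per group, adjusted p = 5.98e-07). CDC45 (−0.39 ± 0.08) and RFC4 (−0.52 ± 0.11) fell by less. A further fall was that of PRIM1, which overlaps NACA on the same strand (mean counts 3023 against 48800). Over the list 4 of 38 genes fell and 1 (GINS1) rose, or 4 and 2 adjusted over the list alone. Its median was 0.05, its mean −0.03 and its tested direction down (list adjusted p = 0.511, and 0.892 with an estimated correlation). Cholesterol genes rose in 6 of 24 cases, or 7 adjusted over the list alone, with HMGCS1 at 1.14 ± 0.23, SQLE at 0.69 ± 0.11 and HMGCR at 0.60 ± 0.13. The median was 0.14 (list adjusted p = 0.0355, adjusted p = 0.129 with an estimated correlation). SCD (−0.76 ± 0.07) and FADS1 (−0.67 ± 0.08), which desaturate fatty acids, fell. NPM1 fell (−0.52 ± 0.10), with 11 of 33 genes of the MYC program, or 12 adjusted over the list alone. The median was −0.21 (list adjusted p = 3.64e-05, adjusted p = 0.129 with an estimated correlation). In all, 1202 genes were higher and 1040 lower, 10.9% of those tested. Of all tested genes, 33.3% had no overlap between groups, against 10% by chance. Without untreated replicate 3 the higher count was 771, and without treated replicate 2 the number of called lists was 8 in place of 13.

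The ATF4 list fell in all 3 lines with both settings of the correlation. Over single genes, STC2 (−4.76 ± 0.16, −2.94 ± 0.14 and −3.70 ± 0.14 in MV4-11, Molm-13 and Molm-14, n = 3 per group), the intermedin gene ADM2 (−2.73 ± 0.35, −4.23 ± 0.37 and −3.87 ± 0.36), CBS, TRIB3, PHGDH, ASS1 and the mitochondrial enzyme PCK2 (−1.97 ± 0.17, −1.59 ± 0.16 and −1.55 ± 0.16) were among the largest shared falls. The membrane protein gene GYPC (−2.89 ± 0.12, −2.56 ± 0.12 and −1.88 ± 0.12), the channel subunit KCNG1 (−2.24 ± 0.15, −2.22 ± 0.15 and −2.92 ± 0.15) and FYN (−4.38 ± 0.20, −2.28 ± 0.18 and −1.59 ± 0.18) were others. Shared rises included the matrix protease MMP2 (1.98 ± 0.14, 1.71 ± 0.14 and 1.36 ± 0.14), the complement factor CFP (1.72 ± 0.17, 1.27 ± 0.17 and 1.55 ± 0.17), the adrenergic receptor ADRB2 (1.38 ± 0.12, 1.5 ± 0.12 and 1.23 ± 0.12) and CD36 (1.3 ± 0.17, 3.74 ± 0.19 and 1.34 ± 0.17). PRDM1 (1.47 ± 0.26, 1.66 ± 0.26 and 1.65 ± 0.26), TP53INP1 (1.29 ± 0.15, 1.68 ± 0.16 and 1.32 ± 0.16) and DTX4 (1.77 ± 0.17, 1.43 ± 0.17 and 1.44 ± 0.17) rose too, each with a gene overlapping on the opposite strand. In each of these shared genes and lines, the treated libraries did not overlap the untreated ones. ACVR2B and TGFBR1, further receptors of the activin and TGF-beta family, passed in no line under any alternative. ACVR2A, an activin receptor, did not pass at 1.05, 1.27 and 1.19 (adjusted p = 0.0898, 0.055 and 0.124), with ranges of 0.0366 to 0.226, 0.0184 to 0.175 and 0.0628 to 0.702 over the alternatives. ACVR2A averaged 67.94 counts over all libraries and overlaps ORC4 (1351 counts) on the opposite strand, with the strand setting not stated. In MV4-11 it passed with limma on log2(FPKM + 0.1) (0.045), with library totals alone (0.0366) and without Molm-14 treated replicate 2 (0.0394). In Molm-13 it passed under 7 alternatives: DESeq2 (0.0283), the CPM filter (0.0416), limma on log2(FPKM + 0.1) (0.0401), library totals alone (0.0288), and without Molm-14 treated replicate 1 (0.0401), Molm-14 treated replicate 2 (0.0207) or Molm-13 untreated replicate 1 (0.0184). Whether ACVR2A rose in Molm-13 therefore depends on the method. ACVR1B did not pass in any line in the main analysis; its only pass was in MV4-11 without Molm-13 untreated replicate 1 (0.0388, range 0.0388 to 0.491). Higher expression in all 3 lines was called for 353 genes, against 33.9 under independence (10.4 times). Lower expression was called for 480, against 30.4 (15.8 times). Independence treats every gene as equally likely to be called, but calls depended on abundance. Lower calls numbered 57, 43 and 28 in MV4-11, Molm-13 and Molm-14 among the 4107 weakest genes. Among the 4107 strongest they numbered 1727, 1321 and 448. Higher calls numbered 308, 119 and 6 among the weakest and 673, 845 and 443 among the strongest. In MV4-11 and Molm-13 higher calls peaked at an abundance between these, at 1192 and 966. Both expected counts are therefore too low and both ratios too high, by an amount that was not estimated.

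The response of MV4-11 differed from that of Molm-13 in the hypoxia and ATF4 lists with both settings of the correlation. PFKFB4, a regulator of glycolysis, rose in MV4-11 (0.64 ± 0.12) and fell in Molm-13 (−3.08 ± 0.13). The difference was 3.72 ± 0.18 (n = 3 per group, adjusted p = 7.24e-09). AXL (difference 2.42 ± 0.17, adjusted p = 3.42e-07) and BMPR1A (1.89 ± 0.35, adjusted p = 0.00201) responded more positively in MV4-11, as did HLA-DRA (1.44 ± 0.20, adjusted p = 0.000174). MPO (−1.90 ± 0.16, adjusted p = 1.44e-06), LYZ (−1.40 ± 0.12, adjusted p = 2.47e-06) and CCND3 (−1.14 ± 0.17, adjusted p = 0.000309) responded more negatively there. FLT3 differed by 0.11 ± 0.14 (adjusted p = 0.693). The hypoxia list fell in Molm-13 and was not called in MV4-11, where its list adjusted p was 0.883 (median difference 1.19, list adjusted p = 5.6e-09, and 0.0111 with an estimated correlation). The ATF4 list fell less in MV4-11 (median difference 0.59, list adjusted p = 1.1e-07, and 0.0298 with an estimated correlation). The mean log2 CPM of the hypoxia list was 2.56 in untreated MV4-11 and 4.53 in untreated Molm-13, and 2.56 and 2.85 with treatment. For the ATF4 list these values were 5.39 and 6.65 untreated, and 4.39 and 4.92 treated. Both lists thus differed more between the lines before treatment than after it. Whether the untreated level shaped the responses was not tested. With the preset correlation the mitotic list had the smallest p (median difference −0.73, list adjusted p = 5.32e-11, adjusted p = 0.195 with an estimated correlation). In total 2812 genes differed. Both lines moved the same way in 92.3% of the genes called in both. Across genes, which are not independent replicates, Pearson's r was 0.291 and Spearman's rho 0.437.

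Compared with Molm-14, MV4-11 responded more negatively in cholesterol, NF-kappaB, MYC and p53 target genes. HMGCS1 differed by −1.93 ± 0.32 (n = 3 per group, adjusted p = 0.000461), ACAT2 by −1.76 ± 0.11 (adjusted p = 5.15e-08) and TNF by −1.80 ± 0.14 (adjusted p = 6.86e-07). FLT3 rose more in MV4-11 (difference 0.63 ± 0.14, adjusted p = 0.0039), as did KIT (2.77 ± 0.74, adjusted p = 0.012) and ACVR1 (1.08 ± 0.31, adjusted p = 0.0176). MPO (−2.81 ± 0.16, adjusted p = 2.27e-08), LYZ (−2.33 ± 0.12, adjusted p = 1.42e-08), TFRC (−1.98 ± 0.21, adjusted p = 7.2e-06) and CDC45 (−1.30 ± 0.12, adjusted p = 2.12e-06) responded more negatively in MV4-11. Of the lists, 5 differed with both settings of the correlation. These were cholesterol synthesis (median difference −0.79, list adjusted p = 2.71e-09, and 0.00368 with an estimated correlation) and NF-kappaB targets (−0.76, list adjusted p = 3.75e-05, and 0.00718 with an estimated correlation). The MYC program (−0.51, list adjusted p = 7.88e-08, and 0.0485 with an estimated correlation) and p53 targets (−0.59, list adjusted p = 0.00371, and 0.0361 with an estimated correlation) were others. The ATF4 list fell less in MV4-11 (0.60, list adjusted p = 1.52e-07, and 0.0235 with an estimated correlation). Mean log2 CPM in MV4-11 and Molm-14 was 6.36 and 5.4 untreated against 5.72 and 5.58 treated for cholesterol synthesis. It was 3.36 and 2.28 against 2.59 and 2.4 for NF-kappaB, and 5.39 and 7.14 against 4.39 and 5.32 for ATF4. The p53 targets also lay further apart before treatment (4.87 and 4.21) than after (4.64 and 4.35). The MYC program lay closer before (7.29 and 7.32) than after (6.53 and 7.09). Replication genes differed by a median of −1.01 (list adjusted p = 1.27e-16, adjusted p = 0.0914 with an estimated correlation). In total 5019 genes differed. Of the genes called in both lines, 74.6% moved the same way. Across genes r was 0.0513 and rho 0.105.

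**Figure D3:**
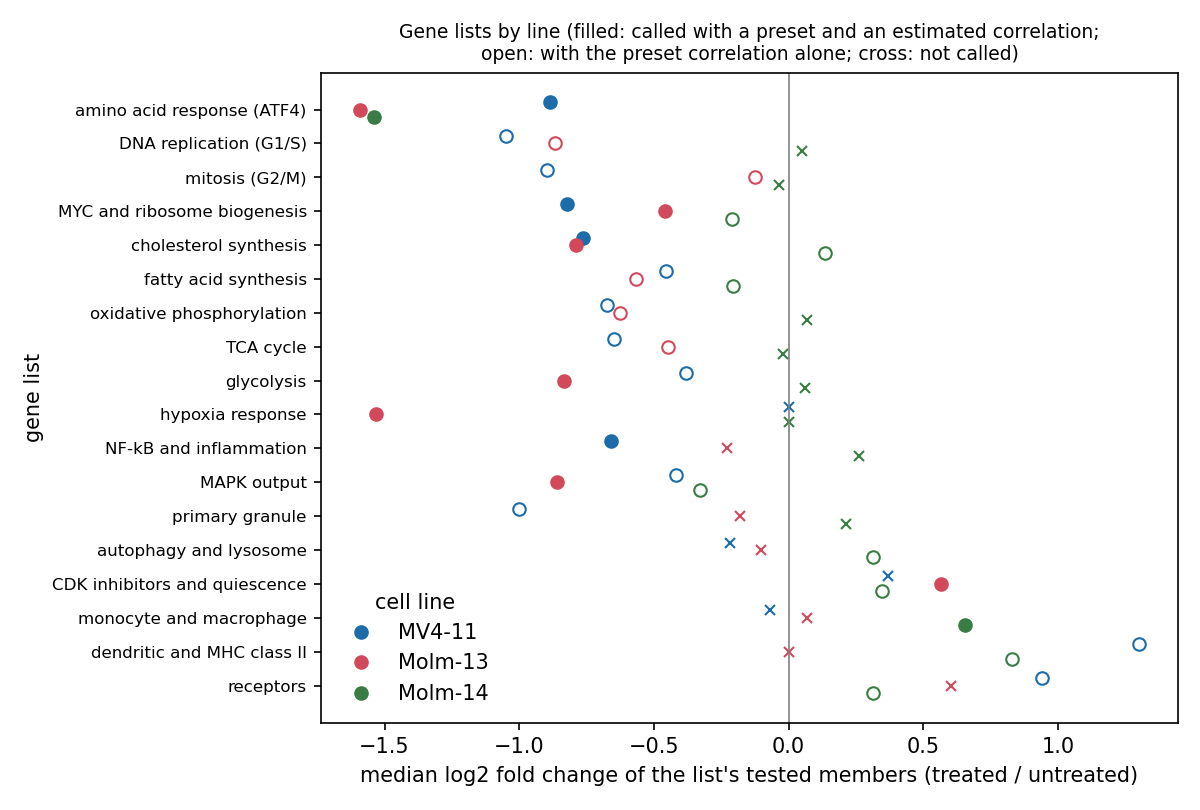
Median log2 fold change (treated over untreated) of 18 gene lists in each line, with filled points for lists called with a preset and an estimated correlation, open points for the preset alone and crosses for lists not called. The ATF4 list lies at −0.88, −1.59 and −1.54 in MV4-11, Molm-13 and Molm-14, and the mitotic list in Molm-13 changes sign from −0.13 to 0.0255 with scaling by library totals alone.

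The responses of Molm-13 and Molm-14 differed in the cholesterol, hypoxia, glycolysis and NF-kappaB lists with both settings of the correlation. HMGCS1 fell in Molm-13 and rose in Molm-14 (difference −2.66 ± 0.32, n = 3 per group, adjusted p = 9.78e-05), and SQLE did the same (−1.20 ± 0.15, adjusted p = 0.000166). SLC2A3 (−1.84 ± 0.10, adjusted p = 3.17e-08), LDHA (−1.17 ± 0.13, adjusted p = 4.42e-05) and PIM1 (−1.47 ± 0.13, adjusted p = 3.29e-06) responded more negatively in Molm-13. The same held for CDC45 (−1.06 ± 0.12, adjusted p = 4.42e-05) and CSF1R (−1.44 ± 0.14, adjusted p = 1.16e-05). MEIS1 (1.23 ± 0.11, adjusted p = 7.64e-06) and FLT3 (0.52 ± 0.14, adjusted p = 0.0239) responded more positively there. The FLT3 difference was lost without Molm-13 untreated replicate 1 (0.0674) or Molm-14 untreated replicate 2 (0.0697) and with the replicate block (0.076), with a range of 0.0027 to 0.076 over the alternatives. Cholesterol synthesis (median difference −0.90, list adjusted p = 3.08e-15, and 0.000283 with an estimated correlation) and hypoxia genes (−1.17, list adjusted p = 1.01e-10, and 0.00302 with an estimated correlation) responded more negatively in Molm-13. Glycolysis (−0.96, list adjusted p = 5.58e-12, and 0.0217 with an estimated correlation) and NF-kappaB targets (−0.48, list adjusted p = 0.00191, and 0.0217 with an estimated correlation) did so as well. Mean log2 CPM in Molm-13 and Molm-14 was 6.79 and 5.4 untreated against 6.01 and 5.58 treated for cholesterol synthesis. It was 4.53 and 3.16 against 2.85 and 3.11 for hypoxia, and 7.07 and 5.98 against 6.29 and 6.14 for glycolysis. NF-kappaB targets lay at 2.91 and 2.28 against 2.54 and 2.4. Each of these lists lay further apart before treatment than after. Whether the untreated level shaped the responses was not tested. The replication list, with the smallest p under the preset correlation, differed by a median of −0.83 (list adjusted p = 3.1e-20, adjusted p = 0.072 with an estimated correlation). In total 2843 genes differed, or 1826 without Molm-13 treated replicate 1. Of the genes called in both lines, 86.1% moved the same way. Across genes, r was 0.119 and rho 0.186.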

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

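The tests of a few abundant genes, of a smaller response in Molm-14, of a mislabelled library and of counting error, and all counts of other splits of the libraries, were chosen after the result was seen, as were the list tests on differences between lines. Each gene and list in the comparisons of pairs of lines below drew attention because the test of the difference between the responses of that pair passed.

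GPSM1, a regulator of G protein signaling, and ADD2, a membrane skeleton gene, rose in MV4-11 (3.35 ± 0.68 and 2.92 ± 0.10) and were called lower in Molm-13. Their differences of log2 fold changes were 9.56 and 8.89. ZNF432, a zinc finger gene, had a difference of 7.78, and ZFP3, another, one of 7.53. All treated Molm-13 libraries had a count of 0 for these 4 genes, so the fitted differences are no bounds. If each count is 1 read, a floor of 3 counts per library put treated Molm-13 at least 3.37-fold lower for GPSM1. On the same condition it was at least 2.93-fold lower for ADD2 and at least 1.24-fold lower for ZNF432. Untreated Molm-13 expression of ZFP3 was under the floor (0.0252 CPM against 0.0417), so no fold is given, and without Molm-13 untreated replicate 3 the difference was 3.72 (adjusted p = 1, range 4.18e-06 to 1 over the alternatives). The call of ZFP3 in Molm-13 lay at the threshold (adjusted p = 0.05 as rounded, range 0.0203 to 1). Of the alternatives that gave a value, it held only with the CPM filter (0.0427), the replicate block (0.0455), the robust fit (0.0484) and without Molm-13 untreated replicate 1 (0.0263) or 2 (0.0203). In total 2812 genes, 12 lists (2 with an estimated correlation) and 125 named genes differed between MV4-11 and Molm-13.

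Between MV4-11 and Molm-14, KIF17, a kinesin motor gene, rose in MV4-11 (3.29 ± 0.32) and fell in Molm-14 (−2.13 ± 0.30), a difference of 5.43 ± 0.44 (adjusted p = 7.64e-07). SERPINB10, a protease inhibitor gene that overlaps SERPINB2 on the same strand, moved the other way (−2.78 ± 0.50 and 3.01 ± 0.55, difference −5.79). ZNF331 (3.57 ± 0.71 and −2.27 ± 0.66) had a difference of 5.84, and PLA2G4B, which shares its strand with a readthrough gene, one of 6.50 (3.06 ± 0.93 and −3.44 ± 1.00). The fall of ZNF331 in Molm-14 (adjusted p = 0.0396, range 0.00437 to 0.134) was lost without Molm-14 treated replicate 1 (0.134), 2 (0.0539) or 3 (0.128), untreated replicate 1 (0.0554), 2 (0.0934) or 3 (0.102), or Molm-13 untreated replicate 1 (0.0508), 2 (0.0517) or 3 (0.0521), and with the replicate block (0.113) and limma on log2(FPKM + 1) (0.0578). The rise of PLA2G4B in MV4-11 (adjusted p = 0.017, range 0.00138 to 0.189) was lost without MV4-11 treated replicate 1 (0.123) or untreated replicate 1 (0.0678), and with the replicate block (0.189) and only the libraries compared (0.0692). Its fall in Molm-14 (adjusted p = 0.0382, range 0.00157 to 0.586) was lost without Molm-14 treated replicate 1 (0.131), 2 (0.118) or 3 (0.0862), untreated replicate 1 (0.0931) or 3 (0.111), or Molm-13 untreated replicate 2 (0.0505), and with the replicate block (0.165) and limma on log2(FPKM + 1) (0.586) or log2(FPKM + 0.1) (0.229). In total 5019 genes, 18 lists (5 with an estimated correlation) and 190 named genes differed.

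Between Molm-13 and Molm-14, the glycolysis genes PFKFB4 and ALDOC fell in Molm-13 (−3.08 ± 0.13 and −2.93 ± 0.18) and rose in Molm-14 (0.63 ± 0.12 and 0.62 ± 0.17), with differences of −3.71 and −3.55. The rise of ALDOC in Molm-14 (adjusted p = 0.0259, range 0.00635 to 0.135) was lost without Molm-14 treated replicate 1 (0.0915) or 2 (0.0996) or untreated replicate 1 (0.108), 2 (0.0553) or 3 (0.0611), and with no low-count filter (0.0532) and the replicate block (0.135). TMEM45A, a membrane protein gene, had a difference of −3.20 (−1.84 ± 0.21 and 1.36 ± 0.21). MGAT3, a glycosylation enzyme gene, rose in Molm-13 (2.68 ± 0.50) and had a count of 0 in all treated Molm-14 libraries. If each count is 1 read, MGAT3 was at least 1.27-fold lower there against the floor of 3 counts per library. Its fitted difference was 7.62, and its fall in Molm-14 (adjusted p = 0.0147, range 0.000683 to 0.973) was lost without Molm-14 untreated replicate 2 (0.0662) and with limma on log2(FPKM + 1) (0.973) or log2(FPKM + 0.1) (0.81). In total 2843 genes, or 1826 without Molm-13 treated replicate 1, 16 lists (4 with an estimated correlation) and 140 named genes differed.

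Replication genes such as CDC45 fell in MV4-11 and Molm-13 but hardly in Molm-14, where the mean change of the list was −0.032 ± 0.0229 SE against −0.865 ± 0.0263 in Molm-13. A smaller response of every gene in Molm-14 is argued against by the ATF4 list, whose change in Molm-14 was 1.05 times that in Molm-13, while the ratio for the replication list was 0.0369 (SE of the difference 0.0446). A single mislabelled library is argued against because 18 of 18 libraries were closest to another library of their own group. This check cannot detect a whole group or line that carries the wrong name. Molm-14 stood apart from the other lines without treatment as well. Spearman correlations of untreated group means were 0.965 for MV4-11 with Molm-13, 0.92 for MV4-11 with Molm-14 and 0.927 for Molm-13 with Molm-14. The identity of the lines was not tested. A low untreated level of replication genes stays open, since untreated Molm-14 lay at −0.687 relative to untreated Molm-13 (6.36 against 7.05 mean log2 CPM), between the bounds set for and against it. A difference between the lines in how their cell cycle depends on FLT3 may also contribute and was not tested.

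Weakly expressed genes were higher in treated MV4-11, with a median change of 0.69 among the 4107 weakest genes and −0.21 among the 4107 strongest, and in Molm-13 these medians were 0.10 and −0.12. Depth is argued against, since after thinning to the total of the smallest library treated libraries still had 1520 more genes with 10 counts in MV4-11 and 514 more in Molm-13. The test of a few abundant genes taking counts gave ratios of 0.0283 in MV4-11 and 0.307 in Molm-13. It set their share of unscaled counts against changes after TMM scaling, which is meant to remove such a shift. It therefore cannot decide in either line. Stray genomic DNA may contribute, since of 851 olfactory receptor genes, taken to be silent in blood cells, 37, 33 and 29 were counted in treated and 25, 26 and 20 in untreated MV4-11 libraries (ratio 1.39, and 1.16 in Molm-13, where it stays open). A rise of weakly expressed genes by treatment would raise these counts as well, so they cannot tell the explanations apart. An effect of TP-0184 on weakly expressed genes stays open as well and was not tested.

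Some genes jumped at least 8-fold between replicates of 1 group, 201 genes in 333 pairs of gene and group with a group mean of at least 5 CPM. A faulty library is argued against by the largest share of jumps in 1 library, 7.81%. Counting error is argued against, since 72 of the jumps lay above the median mean count of all pairs at that level, 2230 counts, where it allows no 8-fold jump. The share of pairs with a jump above that median was 0.276 ± 0.0367 SE times the share below it. Reads moved between genes that overlap on the same strand may be a source, since 45.8% of jumping genes had such an overlap against 6.5% of 354 other genes of like expression, a ratio of 7.04. Called genes with a jump in that line were 5 in MV4-11 (PLA2G4B, HELLPAR, AP000356, STON1 and DERPC), 4 in Molm-13 (RFX7, PDCD6-AHRR, FARP2 and TENT5A) and 3 in Molm-14 (ALB, SERPINA1 and AP001972). The design gives no biological explanation for a jump between replicates, and none was tested.

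The 6 libraries of a line make 10 splits into groups of 3, too few for a share under 0.05. The real split called 7898, 6135 and 2242 genes in MV4-11, Molm-13 and Molm-14, and the highest other split 48, 1 and 6, so 1 of 10 splits reached the real count in each line. For lists the real split called 18, 17 and 13 and the highest other 14, 12 and 11, again 1 of 10. Over 60 joint draws of splits in all 3 lines, only the real draw reached the genes higher and lower in all 3 lines (353 and 480, highest other 0 and 0). It was also the only 1 to reach the differences between MV4-11 and Molm-14 (5019, highest other 2133) and between Molm-13 and Molm-14 (2843, highest other 161). The other draws mix treated and untreated libraries, which makes few calls likely. These counts therefore bear only on whether treatment had an effect in any line. They cannot show that the lines share a response or that their responses differ. For MV4-11 against Molm-13, 5 draws including the real one gave at least 2812 differences (highest other 3567), so chance cannot be excluded by this count. The 4 other draws kept the treated and untreated split in at least 1 line, and the highest count in the 44 draws that kept it in no line was 2.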

How the results depend on the processing

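The robust fit, the scaling by library totals alone, the restriction to genes without overlap and the list tests on differences were chosen after seeing the data. FLT3, KIT, PIM1 and CHAC1 kept their direction in all lines under all alternatives run. Of 305 named genes with 580 results by gene and line or pair of lines, 558 were called, 457 of these kept their call under all alternatives run on single genes other than leaving out a library, and 470 kept it whichever library was left out. The required 2-fold change and the restriction to genes without overlap were run on counts of genes alone and are not part of the 457. Counts of genes from RLE and upper-quartile scaling, DESeq2, the filters on low counts, the fit of only the libraries compared, the robust fit and library totals alone stayed within 1.5 times those reported.

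Limma on log2 FPKM plus 1 gave 6205 higher genes in MV4-11, and on log2 FPKM plus 0.1 it gave 6258. Scaling by library totals alone moved this count the same way, from 3931 to 5444. Whether these shifts share a cause was not tested. Requiring a 2-fold change, which can only remove calls, left 2212 higher and 1213 lower genes in MV4-11, 1107 and 686 in Molm-13 and 310 and 265 in Molm-14. It left 1284 differences between MV4-11 and Molm-13, 2461 between MV4-11 and Molm-14 and 1070 between Molm-13 and Molm-14, with 58 genes higher and 60 lower in all 3 lines. With an estimated correlation camera called 4, 7 and 2 lists in MV4-11, Molm-13 and Molm-14. Fry, which asks a different question, called 33, 28 and 22.

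Adding the replicate number as a block gave 651 higher and 610 lower genes in Molm-14, 1651 differences between MV4-11 and Molm-13, 1087 between Molm-13 and Molm-14, and 200 higher and 258 lower genes in all 3 lines, and 71 named results lost their call. The deviations of treated and untreated libraries of the same number correlated at −0.0967 to 0.0311, and the highest value, 0.0862, belonged to a pair with different numbers. These values show no strong pairing by number. The labels do not say what a number marks, so a pairing cannot be excluded. The block also used residual degrees of freedom.

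Leaving out 1 library at a time gave 3110 to 3949 higher and 3393 to 4035 lower genes in MV4-11, 2270 to 3105 and 2276 to 3195 in Molm-13, and 771 to 1254 and 735 to 1199 in Molm-14, where 771 came without untreated replicate 3. Differences ranged from 2154 to 3075, from 4194 to 5379 and from 1826 to 3051 for MV4-11 against Molm-13, MV4-11 against Molm-14 and Molm-13 against Molm-14, the lowest of the last without Molm-13 treated replicate 1. Genes higher in all 3 lines numbered 237 to 362 and lower 346 to 529. Called lists numbered 18 to 20, 16 to 18 and 8 to 14, with 8 without Molm-14 treated replicate 2.

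CPT2, a fatty acid oxidation gene called lower in MV4-11 (−0.20, adjusted p = 0.043, range 0.0286 to 0.879), changed sign to 0.0174, 0.0205 and 0.0216 with FPKM plus 1, FPKM plus 0.1 and library totals alone; the cause was not tested. Its call was also lost with RLE (0.0705) and upper-quartile scaling (0.141), no low-count filter (0.0745), the CPM filter (0.0699), the block (0.107) and only the libraries compared (0.16). Of the left-out libraries, the call held without MV4-11 treated replicate 1 or untreated replicate 3, Molm-13 untreated replicate 1 or 3, or Molm-14 treated replicate 3, and was lost without any other (0.0529 to 0.181). ZFP3 in Molm-13 ranged from −4.39 to 0 with 1 library left out and was 0 without Molm-13 untreated replicate 3, which left no count in any Molm-13 library. Genes under 0.0407 to 0.0585 CPM, depending on the library, were not detectable at this depth.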

Other observations

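Some genes outside the main programs moved the same way in all 3 lines. The unfolded protein response factor XBP1 fell in MV4-11, Molm-13 and Molm-14 (−1.31 ± 0.08, −1.12 ± 0.08 and −0.93 ± 0.08, n = 3 per group), while its list was called in MV4-11 (13 of 18 fell and 3, HERPUD1, DNAJB9 and ERN1, rose by both counts, over all genes and adjusted over the list alone, list adjusted p = 0.000867, adjusted p = 0.176 with an estimated correlation). The linker histone gene H1-0, which marks cells leaving the cycle, rose (1.74 ± 0.14, 0.61 ± 0.13 and 0.69 ± 0.13), as did the autophagy gene GABARAPL1 (1.37 ± 0.12, 0.93 ± 0.12 and 0.91 ± 0.12), the fatty acid oxidation enzyme CPT1A (0.55 ± 0.08, 0.93 ± 0.08 and 0.42 ± 0.08) and the integrin ITGB7 (0.91 ± 0.10, 0.95 ± 0.10 and 1.05 ± 0.10). TRAC, a T-cell receptor segment, fell (−1.29 ± 0.12, −1.46 ± 0.12 and −0.57 ± 0.12). IGHM in Molm-14 had a count of 0 in all untreated libraries and was at least 5.45-fold higher with treatment, against a floor of 3 counts per library. Likewise S100P in treated MV4-11 was at least 30.4-fold lower. Both folds are bounds only if each count is 1 read.

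Genes downstream of activin and BMP receptors gave no common direction. The matrix protein TGFBI, a TGF-beta target, rose in MV4-11 (3.98 ± 0.46, adjusted p = 6.4e-06), and ID2, a BMP target, rose in Molm-14 (1.25 ± 0.10) and fell in Molm-13 (−0.54 ± 0.09). The signal carriers SMAD3 (1.28 ± 0.10 and 0.66 ± 0.10) and SMAD5 (1.09 ± 0.16 and 0.75 ± 0.16) rose in MV4-11 and Molm-13, SMAD1 fell in MV4-11 (−1.66 ± 0.20), and SMAD1 had a count of 0 in all Molm-14 libraries, where up to 3 counts per library cannot be excluded. Of 15 BMP and TGF-beta targets, 5 rose (SERPINE1, TGFBI, SKIL, SMAD6 and SKI) and 2 fell (BAMBI and ID1) in MV4-11, or 7 and 2 adjusted over the list alone. In Molm-13, 4 fell (SMAD7, ID2, ID1 and SKIL), and in Molm-14, 2 rose (SMAD7 and ID2), the same counts when adjusted over the list alone. The list was not called in any line (list adjusted p = 0.352, 0.174 and 0.463). Its median was 0.127 and its mean −0.242 in Molm-14, where the tested direction was up.

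Reference genes of the kind used to scale PCR assays fell in 9 of 13 cases in MV4-11, or 10 adjusted over the list alone (median −0.52, list adjusted p = 0.000805, adjusted p = 0.176 with an estimated correlation), and in 6 of 13 in Molm-13 with 2 rises (B2M and POLR2A), or 7 and 2 adjusted over the list alone. The median was −0.28 (list adjusted p = 0.0196, adjusted p = 0.334 with an estimated correlation). Their medians were below 0 in both lines under every scaling run. In Molm-14 the list was not called, with 3 genes higher and 1 lower. Its median there was 0.06 (list adjusted p = 0.661, adjusted p = 0.892 with an estimated correlation). GAPDH, a glycolytic gene used for the same purpose, fell in all 3 lines (−0.99 ± 0.11, −1.02 ± 0.11 and −0.65 ± 0.11). Mitochondrially encoded genes made up 6.31% of the counts of MV4-11 treated replicate 2, against 4.02% to 4.88% in the other MV4-11 libraries.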
